A study of Caenorhabditis elegans with 4 samples.

How the data were processed

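Binding of HPL-2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites. HPL-2 is a worm member of the heterochromatin protein 1 family, which binds chromatin. The strain carried HPL-2 fused to GFP under the ges-1 promoter, which is active in the intestine, and the n745 mutation of lin-35, the worm homologue of the retinoblastoma tumour suppressor. Per the labels, animals were starved first-stage larvae (L1) kept at 20 degrees Celsius, crosslinked with formaldehyde, and precipitated with antibodies against GFP. The series holds 4 samples, 2 ChIP samples and 2 Input samples (genomic DNA from the same extracts before precipitation). Peak lists were used for each ChIP sample and for the combined series. No list of an Input sample was used here.

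The peaks were called by the authors with PeakSeq, which compares ChIP reads with a control library, per the file headers and the source column of the lists. The deposited lists give each peak's first and last base and 1 q-value, and no count of reads, fold enrichment or summit. The coordinates are on WormBase WS220, per the file headers. Comment lines in the deposited lists mark 3 combined peaks, 2 replicate 1 peaks and 1 replicate 2 peak as altered by a conversion from another build. The caller's version and settings, the aligner, the original build and the way the combined list was made are not given in the sources used here. Each ChIP sample has its own list. The combined list is neither the union nor the intersection of the ChIP lists, because it holds 922 peaks that are in neither and lacks 29 replicate 1 peaks. All q-values lay under 0.01, neighbouring peaks in a list were at least 201 bp apart, and any threshold or merging behind this is not given in the sources used here. Read depth is unknown, so the number of peaks in a list cannot be corrected for it.

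Peaks were ranked within a list by q-value, expressed as -log10 q, and q-values were never compared between lists. The design, the tests and the rule for named peaks were fixed before the data were examined. The design had assumed a score per peak, and the q-value took its place. A peak was counted as found in another list when it overlapped a peak there by 1 bp or more. Shares carry exact (Clopper-Pearson) 95% confidence intervals, which treat peaks as independent and cover counting error only. Overlap between the ChIP lists was set against 1000 circular shifts of the replicate 2 list along each chromosome (one-sided permutation test). The share of autosomal peak midpoints in the arms, taken as the outer segments when each chromosome is divided into 3 equal segments, was set against 10000 circular shifts (two-sided). Clustering was measured as peaks whose next peak along the chromosome had its midpoint within 5 kb, against 10000 random placements (one-sided). Medians were compared by two-sided permutation tests with 100000 resamples, or by exact enumeration where a group held 10 or fewer peaks. The share of peaks on each of the 6 chromosomes was compared with its share of length by two-sided exact binomial tests with Benjamini-Hochberg adjustment over the 6. The length of a chromosome was taken as the furthest peak end in any of the 3 lists. Shares on X among the strongest peaks were compared by Fisher's exact test. Whether peak width accounts for the share on X among the strongest peaks was tested by moving the X label among groups of 20 peaks of similar width (one-sided permutation test, 100000 resamples). Peaks are not replicates of the experiment, so these p-values describe the lists, not the spread between animals or cultures. The labels do not say whether the ChIP samples came from separate cultures.

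The rule for named peaks took the 25 peaks of the combined list with the smallest q-values, the 5 strongest of those in both ChIP lists, and genes of lists fixed in advance. The gene table at hand is on assembly WBcel235, another build than WS220. Peaks are therefore named by position, and the planned tests of position relative to genes and of gene lists were not run. The alternatives tried were either ChIP list in place of the combined one, peaks in both lists, the stronger part of a list split at its median q-value, other overlap rules, distances, arm definitions and random placements. Leaving out peaks under 100 bp, the number of close neighbours of a ChIP list that overlap the same combined peak and the test without them, the comparison of X with the autosomes among the strongest peaks, its alternatives and its test at matched width, and the shares in arms of single chromosomes were added after the data were seen.

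The functions were tested on simulated lists placed on these chromosomes. With 141 of the peaks of a list the size of replicate 2 placed on peaks of a list of 1288 peaks, 143 were found. Of 100 pairs of unrelated lists, 2 passed the overlap threshold of 0.05. For lists of 2162 peaks made with 80% of peaks in arms, 80.3% were recovered, and 6 of 100 uniform lists passed the arm test. In 100 lists of 2162 peaks, strength came from width and random noise alone, and X peaks were made 2 times as long. X held 47.7% of the 25 strongest peaks of these lists on average, and 0 lists passed the test at matched width. That setting is more extreme than the combined list, where the median was 446 bp on X and 391 bp on autosomes. No list with a true X effect was simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.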

Results

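The series mapped chromatin recovered with antibodies against GFP from starved L1 larvae carrying the n745 mutation of lin-35. The larvae expressed HPL-2::GFP from the intestinal ges-1 promoter. No ChIP sample without the tagged protein is in the series, so non-specific recovery was not measured. The authors deposited 1288 peaks for ChIP replicate 1, 177 peaks for ChIP replicate 2 and 2162 peaks in a combined list. The peaks covered 833 kb, 119.7 kb and 1264 kb, or 0.834%, 0.12% and 1.27% of the length spanned by peaks. Median peak width was 439 bp in replicate 1 (middle 50% of peaks, 323 to 710 bp), 535 bp in replicate 2 (369 to 838 bp) and 398 bp in the combined list (292 to 629 bp). The widest peak spanned 7787 bp, and 118 combined peaks were shorter than 100 bp. Read depth behind these lists is unknown.

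The first comparison asks how far the ChIP replicates marked the same regions. Nearly every region of the shorter list was present in the longer one: 163 of the 177 replicate 2 peaks (92.1%, 95% confidence interval 87.1 to 95.6%) overlapped a replicate 1 peak. After circular shifts of the replicate 2 list, 3.05 peaks overlapped on average and at most 14 did (permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction, 150 of the 1288 replicate 1 peaks (11.6%, 9.94 to 13.5%) were found in replicate 2. The strongest replicate 1 regions were found again and the weak ones mostly were not. All 25 of the replicate 1 peaks ranked 1 to 25 were found in replicate 2, against 51 of 75 at ranks 26 to 100, 44 of 200 at ranks 101 to 300, and 13 of 300 at ranks 301 to 600. At ranks 601 to 1288, 17 of 688 peaks (2.47%, 1.45 to 3.93%) were found.

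Replicate 1 peaks that were found in replicate 2 had a median -log10 q of 12.1, against 2.94 for the 1138 others, a difference of 9.19 (permutation p = 1e-05, the smallest that 100000 resamples can give). They were also wider by 429 bp in median (841.5 against 412.5 bp, permutation p = 1e-05). In replicate 2, the 163 shared peaks had a median -log10 q of 3.26 and the 14 others 2.25, a difference of 1.01 that did not pass the test (permutation p = 0.0564). It passed when an overlap of at least 0.5 of the shorter peak was required (difference 1.03, permutation p = 0.0446), and was 0.094 with midpoints within 200 bp as the rule (permutation p = 0.671). The combined list comes from the same ChIP samples, so its order is not independent of theirs and was not taken as a further test. Its 150 peaks found in both ChIP lists had a median -log10 q of 17.3 and a median width of 905 bp, the 1090 found in 1 ChIP list had 4.17 and 455 bp, and the 922 found in neither had 2.38 and 319.5 bp.

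**Figure D1:**
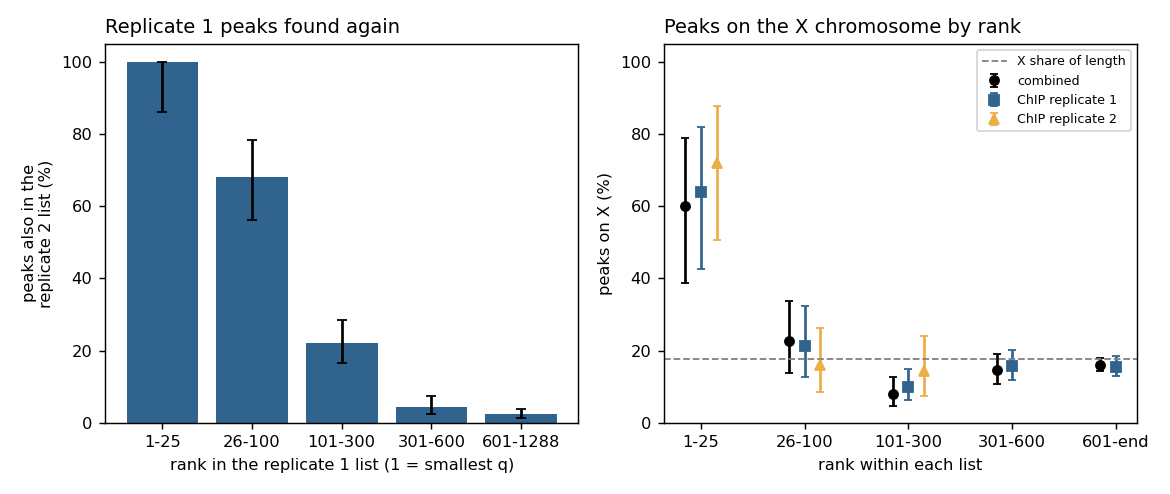
Left, share of replicate 1 peaks (%) that overlap a replicate 2 peak, by rank in the replicate 1 list. Right, share of peaks (%) on X by rank within each list, with the X share of chromosome length (17.6%) dashed (the replicate 2 list ends at rank 177); bars (left) and points (right) are shares and whiskers exact 95% confidence intervals. The share found again falls from 100% at ranks 1 to 25 to 2.47% at ranks 601 to 1288, and X holds 60% to 72% of the 25 strongest peaks of each list.

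The strongest regions of the combined list were on the X chromosome and on a few broad autosomal segments. All 25 of the combined peaks with the smallest q-values were found in both ChIP lists, and 15 of them were on X, 3 on IV, 3 on V, 2 on II, 1 on I and 1 on III. The strongest peak lay on chromosome V from 8758074 to 8764177 (WormBase WS220), a segment of 6104 bp with a q-value of 1.28e-163. Replicate 1 had it as 1 peak of 5828 bp, also its strongest, and replicate 2 as 4 separate peaks, the best of them at rank 23. The second lay on X from 2996220 to 2997851 (1632 bp, q-value 1.39e-107) and ranked 2 in replicate 1 and 3 in replicate 2. The third, on chromosome I from 7079094 to 7086206 (7113 bp, q-value 2.44e-105), ranked 3 in replicate 1 but 110 in replicate 2. The next peaks in rank, 4 and 5, were on X, from 1503334 to 1505213 (1880 bp, q-value 1.46e-103) and from 16929318 to 16931988 (2671 bp, q-value 2.6e-95). These 5 were also the 5 strongest peaks found in both ChIP lists. In replicate 2, the 15 X regions among the 25 strongest had best ranks from 2 to 20, and the autosomal ones from 21 to 110. By best rank, the broad autosomal segments thus stood out less in replicate 2 than the X regions. However, replicate 2 held most of these autosomal segments as several peaks and nearly all of the X regions as 1 peak. The autosomal segments it held as 1 peak, at I 7079094, II 12052820 and IV 8431042, ranked 110, 51 and 21. A weaker signal was not told apart from the splitting of a segment into several peaks.

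The other X regions among the 25 strongest began at bases 14525246, 8035843, 11789606, 4208416, 6295829, 12362575, 11093636, 16055863, 9465307, 11605233, 13699926 and 4006843. Their q-values ran from 2.03e-93 for the first to 3.92e-51 for the last. The region at X 14525246 to 14526898 was the strongest X peak of replicate 2, at rank 2 in that list with a q-value of 1.25e-33. On chromosome IV the strong regions were 11913202 to 11916603, 291708 to 296250 and 8431042 to 8433432, with widths of 3402, 4543 and 2391 bp. Chromosome V also held 6222317 to 6230103, the widest peak of the list (7787 bp, rank 12), and 723856 to 728296 (4441 bp). Chromosome II held 12052820 to 12056730 (3911 bp) and 6345275 to 6349170 (3896 bp), and chromosome III 5501266 to 5506684 (5419 bp). In replicate 2 the best ranks of these autosomal regions were, in the same order, 35, 24, 21, 108, 48, 51, 43 and 67. The region at V 6222317 had a best q-value of 0.00166 there. The transgene adds sequence of ges-1, hpl-2 and unc-119 to the genome, so a peak at those places need not mark binding to the native locus. Whether any named peak lies there was not determined, because gene positions on this build were not used here. Of the 25 strongest peaks of each ChIP list, 19 overlapped a peak among the 25 strongest of the other.

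**Figure D2:**
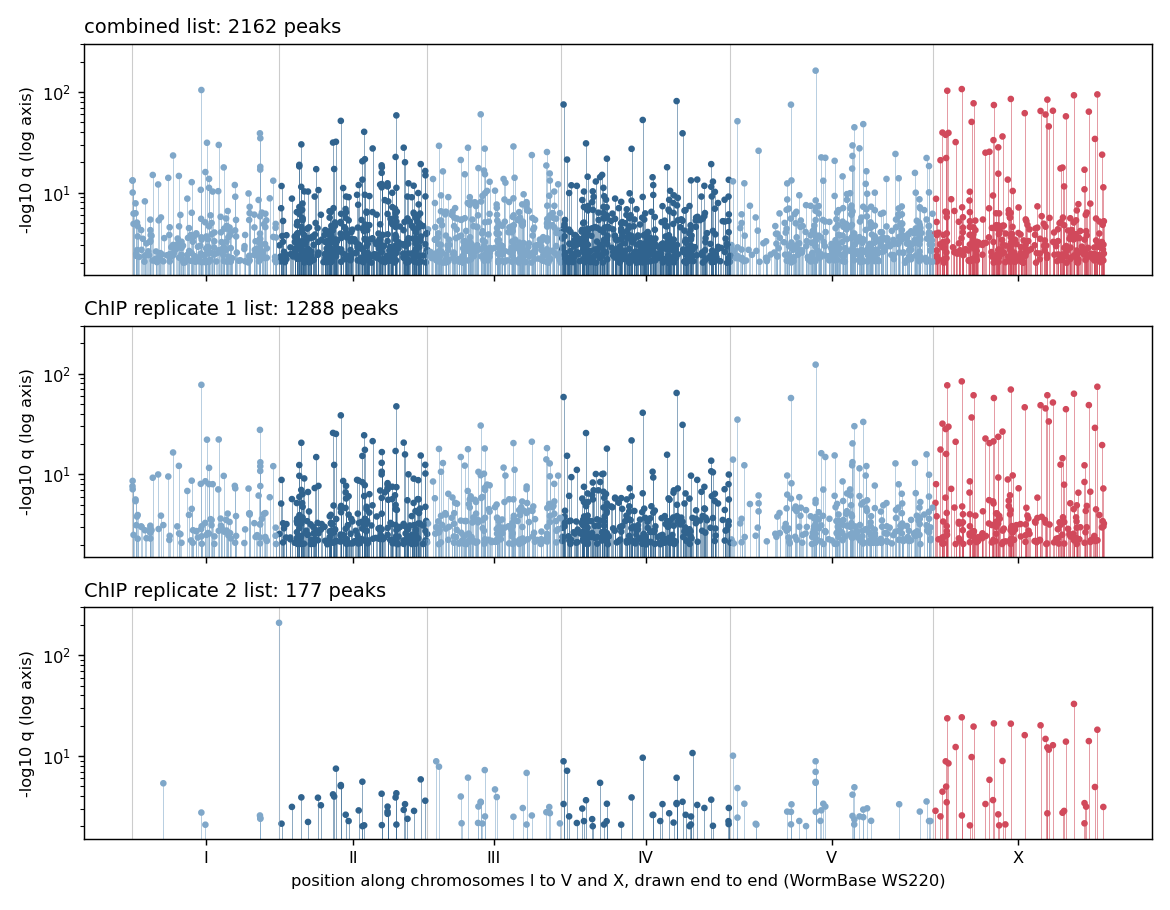
Peak strength (-log10 q, log axis) along chromosomes I to V (blue shades) and X (red), drawn end to end, in the combined list and each ChIP list; each point is 1 peak at its midpoint. Strong peaks recur along X in both ChIP lists and in the combined list, which comes from the same samples. Replicate 2 has 1 peak at the right end of chromosome I (q-value 2e-211) that the other lists lack.

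X was over-represented among the strongest peaks and not over the whole combined list. In the combined list 15 of the 25 strongest peaks (60%, 38.7 to 78.9%) were on X, against 328 of the other 2137 (15.3%, 13.8 to 16.9%; Fisher's exact test, two-sided p = 5.45e-07). The same held in replicate 1, with 16 of 25 against 190 of 1263 (Fisher's exact p = 5.78e-08), and in replicate 2, with 18 of 25 against 23 of 152 (Fisher's exact p = 1.83e-08). The combined list comes from the same ChIP samples, so its test is not independent of theirs. Of the 25 strongest peaks of each ChIP list, 19 overlapped one among the 25 strongest of the other. The tests of the ChIP lists thus rest largely on the same regions. Among the 100 strongest combined peaks, which include those 25, the share on X was 32%. At ranks 26 to 100 alone, 17 of 75 were on X (22.7%, 13.8 to 33.8%), a range that spans its 17.6% of the length. X had 8% of ranks 101 to 300. Among the 25 widest peaks 2 were on X (8%, 0.984 to 26.0%), against 341 of the other 2137, a difference that did not pass the test (Fisher's exact p = 0.41). Among peaks chosen by q-value, those on X were narrower: the 15 among the 25 strongest had a median width of 1380 bp and the 10 autosomal ones 4492 bp (exact permutation test, two-sided p = 0.000101). In replicate 2 the medians were 939.5 bp for 18 X peaks and 1142 bp for 7 autosomal peaks, a difference that did not pass the test (exact permutation p = 0.34). Replicate 2 held several broad autosomal regions as more than 1 peak, which limits both this comparison and its share of 18 of 25 on X. Over all combined peaks the X median was 446 bp and the autosomal median 391 bp, a difference that was not tested. The comparisons of X with the autosomes among the strongest peaks were chosen after the lists had been seen.

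**Figure D3:**
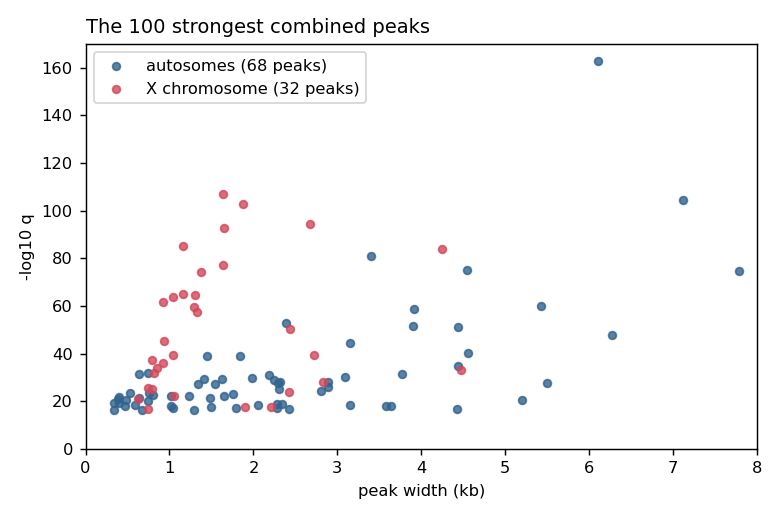
Peak width (kb) against -log10 q for the 100 strongest combined peaks, 32 on X (red) and 68 on autosomes (blue); each point is 1 peak. The X peaks among the 25 strongest have a median width of 1380 bp and the autosomal ones 4492 bp, and the widest peak, 7787 bp, is autosomal.

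Over all peaks, regardless of strength, chromosome I held few peaks for its length and chromosome IV many. The combined list held 21.7 peaks per Mb. Chromosome I had 15.1 per Mb, or 10.5% of peaks (9.28 to 11.9%) on 15.1% of the length (log2 ratio -0.52, exact binomial test, adjusted p = 4.85e-09). Chromosome I was below its share in replicate 1 too, with 115 of 1288 peaks (log2 ratio -0.76, exact binomial test, adjusted p = 3.09e-10), and in replicate 2, with 7 of 177 (log2 ratio -1.93, exact binomial test, adjusted p = 2.54e-05). Chromosome IV had 27.4 peaks per Mb (log2 ratio 0.34, exact binomial test, adjusted p = 1.11e-07) and chromosome II 25.6 per Mb (log2 ratio 0.24, exact binomial test, adjusted p = 0.000822). Both passed in replicate 1 and not in replicate 2, where the log2 ratios were 0.33 and 0.20. Chromosome V, at 18.9 peaks per Mb (log2 ratio -0.20, exact binomial test, adjusted p = 0.00347), passed in replicate 1 and not in replicate 2, nor in the stronger part of the combined list (log2 ratio -0.10, adjusted p = 0.277). Chromosomes III (24 per Mb, log2 ratio 0.15, exact binomial test, adjusted p = 0.0423) and X (19.5 per Mb, log2 ratio -0.15, adjusted p = 0.0383) passed in the combined list alone among the 3 lists. In replicate 2 both went the other way, at -0.081 and 0.39, without passing; differences between the lists were not tested. Without the 118 combined peaks under 100 bp, neither III (exact binomial test, adjusted p = 0.0515) nor X (adjusted p = 0.0719) passed. Neighbouring peaks are not independent, so these p-values are too small.

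Chromosome arms and centres in C. elegans differ in repeat content and heterochromatin marks, so peaks were compared between them. In the combined list 1131 of 1819 autosomal peaks (62.2%, 59.9 to 64.4%) lay in the arms, the outer segments of chromosomes divided into 3 equal segments, against a mean of 66.7% after circular shifts (permutation p = 0.019). Replicate 1 had 62.1% and replicate 2 62.5%, and neither list passed the test (permutation p = 0.1 and 0.39). Of the 6 chromosomes tested singly, none passed after Benjamini-Hochberg adjustment; chromosome I had the smallest p, with 60.1% in its arms (permutation p = 0.0406, adjusted p = 0.244).

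Peaks lay close together more often than random placement gave. In the combined list 614 of 2162 peaks (28.4%) had their next peak within 5 kb, against a mean of 229 and a maximum of 281 after random placement (permutation p = 0.0001, the smallest that 10000 placements can give). The ratio of observed to random was 2.68 in the combined list. Replicate 1 had 282 such peaks against 84.5 at random, and replicate 2 had 17 against 1.71 (permutation p = 0.0001 for each). In replicate 2, both neighbours overlapped the same combined peak in 12 of the 17 cases, which leaves 5, or 2.93 times the random mean (permutation p = 0.0255). In replicate 1 this held in 31 of the 282 cases, which leaves 251, or 2.97 times the random mean (permutation p = 0.0001). This check cannot see a broad region that the combined list also holds as several peaks. Neighbouring combined peaks were as little as 204 bp apart, and the 614 combined cases had no such check. Clustering of separate regions was therefore not told apart from broad regions split into several peaks. Among combined peaks found in both ChIP lists, 6 of 150 (4%) had a close neighbour, against a mean of 1.24 and a maximum of 7 (permutation p = 0.001).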

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

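Of 77 values under alternative settings, 54 planned and 23 chosen after seeing the data, 50 kept their direction and their side of the threshold or, for numbers of chromosomes past it, stayed within 1.5 times the main number (6 against 4 does, 6 against 3 does not). The later ones leave out short peaks or concern X among the strongest peaks. Unless noted, the cause of a move was not tested. Overlap of the ChIP lists passed the test under every setting tried, and the clustering test likewise, although in replicate 2 both neighbours overlapped the same combined peak in 12 of 17 cases. Whether the combined list itself splits broad regions into close neighbours was not tested. With midpoints within 200 bp, 59.3% of replicate 2 peaks were found in replicate 1 in place of 92.1%. In replicate 2, the difference of median -log10 q between shared and other peaks was 1.03, past the threshold, when an overlap of at least 0.5 of the shorter peak was required (permutation p = 0.0446), and 0.094 with midpoints within 200 bp (permutation p = 0.671). The 6 chromosomes past the threshold became 4 and 1 when 1 replicate was left out (replicate 2 and replicate 1), 1 among peaks in both lists and 3 in the stronger part of the list; these lists are shorter, which by itself lowers the number. The log2 ratio of chromosome III ranged from -0.081 to 0.13 with 1 replicate left out, and that of X from -0.14 to 0.39, with 0.48 among peaks in both lists; both chromosomes lost their call in the stronger part of the list (exact binomial test, adjusted p = 0.277 and 0.091) and without peaks under 100 bp (0.0515 and 0.0719). Chromosome V lost its call in the stronger part (exact test, adjusted p = 0.277), and II, IV and V among peaks in both lists (0.258, 0.283 and 0.258). The share of autosomal peaks in arms no longer passed with 1 replicate left out (62.1% to 62.5%), among peaks in both lists (63.7%) or in the stronger part of the list (62.7%). These shares moved little from 62.2%, on fewer peaks, and the test was passed without peaks under 100 bp (61.6%, permutation p = 0.0084). Ranking by width in place of the q-value put 8% of the 25 widest peaks on X in place of 60%. With 1 replicate left out, the X minus autosome difference of median width was from -3058 bp to -202.5 bp, the latter, without replicate 1, short of the threshold. The tests relative to genes and of gene lists, with their alternatives, were not run, since the gene table is on another build. No paired analysis was possible because no peak list of an Input sample was used and the results come from peak positions, not from a fit across samples. Unknown read depth limits comparisons of peak numbers between lists.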

Other observations

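The tests of explanations in this part, and the regions named in it beyond the 25 strongest, were chosen after the results had been seen. The combined list held 75 peaks at least 2 kb wide, 19 on V, 17 on II, 12 on X, 11 on III, 9 on I and 7 on IV. The X share of these was 16%, against 15.9% of all combined peaks and 17.6% of the length, and 2 of the 4 such peaks of replicate 2 were on X. Of the 10 widest, 4 were on chromosome V: 6222317 to 6230103 (7787 bp), 13653544 to 13659810 (6267 bp), 8758074 to 8764177 (6104 bp) and 10713306 to 10718498 (5193 bp). The last had no peak in replicate 2. The strongest combined peak with no peak in either ChIP list was also on V, from 12442679 to 12443996 (1318 bp, rank 272, q-value 3.89e-08).

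The X chromosome held 15 of the 25 strongest combined peaks. Longer peaks can reach smaller q-values, but moving the X label among peaks of similar width gave a mean of 4.99 X peaks and at most 13 (permutation p = 1e-05, the smallest that 100000 resamples can give), with 5.35 against 16 in replicate 1 and 7.64 against 18 in replicate 2 (p = 1e-05 in each), which argues against width as the whole cause. A higher copy number or scaling of the whole X would raise weak X peaks as well. X held 15.1% (13.6 to 16.7%) of the combined peaks below rank 100, under its 17.6% of the length. Other chromosomes also departed from their share of length, with 10.5% of combined peaks on 15.1% for I and 22.1% on 17.5% for IV. Length is thus a rough baseline, and the share on X does not exclude such a cause. A candidate explanation is that the 15 X peaks among the 25 strongest mark the elements that recruit the dosage compensation complex to X in hermaphrodites. The 15 peaks were spread over 15.4 Mb of X, but positions of those elements were not used here, so the hypothesis stays open, as does non-specific recovery of open or crowded chromatin, which was not tested.

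The strongest peak of replicate 2 lay at the right end of chromosome I, from 15064004 to 15067632 (3629 bp, q-value 2e-211), and neither replicate 1 nor the combined list had a peak there. The right end of chromosome I carries the ribosomal DNA repeats, so reads of a repeated sequence may have been kept in 1 list and removed in the others. The furthest combined peak on chromosome I ended 304 kb to the left. That gap does not decide, since the end of the chromosome may hold no other bound region, and a real difference in replicate 2 cannot be told apart from a difference in processing without reads.

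Replicate 2 had 177 peaks and replicate 1 had 1288. Among called peaks, binding at other regions in replicate 2 is argued against, since 7.91% of its peaks had no replicate 1 peak. This share is the remainder of the 92.1% overlap given above, so it is not a further test. Replicate 2 binding too weak to be called cannot be seen in its list. Of the 100 strongest replicate 1 peaks, 76% were found in replicate 2, against 6.23% of the other 1188 (Fisher's exact test, p = 1.29e-58), which is consistent with lower depth or weaker enrichment in replicate 2. Which of these it was stays open, because read depth is unknown. Other reasons why weak replicate 1 peaks were not found again could give the same pattern and were not tested.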
